A study of Homo sapiens with 30 samples.

How the data were processed

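BEAS-2B cells, an established human bronchial epithelial line, were exposed for 30 min on a rocker to 1 of 4 hookah smoking conditions or kept as controls, and RNA was taken 2 h or 24 h later. The 4 conditions were charcoal burnt without shisha (called charcoal alone here), charcoal with herbal shisha free of tobacco (herbal shisha on charcoal), charcoal with tobacco shisha (tobacco shisha on charcoal), and an electric heater with tobacco shisha (tobacco shisha on the electric heater). Each condition and time had 3 wells, giving 10 groups and 30 libraries. The dose of each was the highest at which no LDH release was seen at 24 h, so doses were set by this measure and not by smoke mass. That limit does not show that the exposures were equally toxic. What the control wells received was not given in the sources used here, nor whether the 3 wells of a group were independent cultures. The p-values therefore measure spread between wells, part of which may be technical.

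Libraries were made from 1 ug of total RNA with a TruSeq RNA kit and sequenced as 50 bp single reads on an Illumina HiSeq. According to the submitters' processing notes, reads were aligned to hg38 with HISAT2 2.1.0 and quantified with StringTie 1.3.4d. The annotation release, filters and strand setting were not given in the sources used here.

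The deposited files hold FPKM values and no read counts, per the file headers. The count-based tests planned before the data were examined were therefore not run, and the fallback written at the same time was used. Each of the 30 files lists 29190 transcripts under 22538 distinct names, and 12977 of the transcripts were 0 in every library. Where a name appeared on several transcripts (6652 repeats), the transcript with the highest mean was kept, which concerned 261 of the genes tested. Of 27 names damaged into date serials, 26 were recovered from their accession. Low values were not whole multiples of a common step, so the number of reads behind a value, and with it the depth per library, is unknown; FPKM sums ranged from 199985 to 220259 per library (median 207976.5). Exact zeros occurred in transcripts with a median of 1 FPKM or more (171 of 8023 such transcripts, touching 100 tested genes); they may be failed estimates, and such genes are given as listed at 0. A whole-series matrix repeats the per-sample files and was not used. GAPDH, ACTB, HMOX1 and DDIT3 were not analysed here, and CYP1A1 was below the filter.

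Values were taken as log2(FPKM + 1). Genes with FPKM of 1 or more in at least 3 libraries were tested (8531 genes) with limma 3.58.1 (trend), with 1 mean per group over all 30 libraries and no replicate block (20 residual degrees of freedom, prior 2.76). The spread of a gene was pooled over the 10 groups. SE and p-values therefore understate the spread of groups whose wells vary more, and overstate that of the others. Each comparison was adjusted by Benjamini-Hochberg over the 8531 genes. A gene was called at an adjusted p below 0.05, and "rose", "fell" and "changed" are used only of called genes. Levels are mean FPKM and SD over 3 wells. Log2 changes come from log2(FPKM + 1) with the SE of the fit, which understates changes of genes near or below 1 FPKM. Alternatives were a replicate block, a fit on the compared groups alone, no filter, a minimum change of 2-fold, a pseudocount of 0.1 (planned for named genes) and leaving out each library in turn, and others added later. Differences between the exposure effects at the 2 times were tested as an interaction in the same fit. No scaling between libraries was added to the FPKM values. Versions were R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

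Genes were named by a rule fixed before the data were examined. For each exposure against its control, the rule took the 6 largest rises and 6 largest falls among called genes with a mean of 1 FPKM or more and all 3 exposed wells beyond all 3 control wells. It also took the 3 members of each list with the smallest p, and CYP1A1, CYP1B1, HMOX1, NQO1, CXCL8, IL6, CDKN1A, MT2A, HSPA1A and DDIT3 in every comparison. Between exposures the 5 largest rises and falls were taken. A gene named in 1 comparison may be given in others. Transcripts listed under small RNA names are not read here as small RNAs. HSPA1A and HSPA1B, like HSPA6 and HSPA7, are near-identical in sequence, so 50 bp reads may be shared between them.

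There were 23 gene lists, also fixed before the data were examined: AHR targets, NRF2 targets, heat shock, metallothioneins, the integrated stress response, endoplasmic reticulum chaperones, immediate early genes, NF-kB targets, interferon response, p53 targets, S phase, G2/M, hypoxia, cholesterol synthesis, epithelial junctions and keratins, extracellular matrix and mesenchymal genes, mucins and secretory genes, ciliated cells, oxidative phosphorylation, and markers of immune, endothelial, fibroblast and red blood cells. Lists with at least 3 tested members were examined with camera, which asks whether the members rank higher or lower than all other genes, at its preset correlation between genes of 0.01. The same test with the correlation estimated from the data is much stricter in lists whose members move together, and its result is printed beside. The fry test asks a different question, whether the members as a set moved in a shared direction, without regard to other genes. List p-values were adjusted over all lists within each family of comparisons. Counts are out of the members tested, which were only part of some lists (10 of 17 endoplasmic reticulum chaperones, 25 of 37 NRF2 targets, 18 of 24 genes of the integrated stress response); the other members were not analysed here. Counts of called members are given over all genes, and adjusted over the list alone where that differs.

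A self-test with known changes added to 50 genes per size recovered 86%, 80% and 76% of genes at a log2 change of 0.5 in 3 comparisons, and 92%, 94% and 96% at a log2 change of 1. The 3 comparisons were charcoal alone at 2 h, the electric heater at 24 h, and the 2 tobacco exposures at 2 h. In each simulation 200 of the 8531 genes were changed and the rest had no shift, and between 7 and 10 of the rest were called falsely. False calls grow with the number of calls, so this number does not carry over to the real comparisons.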

Results

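The 30 libraries covered BEAS-2B bronchial epithelial cells at 2 h and 24 h, from control wells or after 1 of 4 hookah smoke exposures, with 3 wells per group. Between 7598 and 7944 genes per library reached 1 FPKM (median 7791.5), and replicate wells correlated at 0.984 to 0.992. The first principal component carried 32.9% of the variance and the second 21.1%. Keratin, junction and matrix genes were expressed, as were 5 of 11 fibroblast markers, THY1 and COL1A1 among them, and 3 of 14 immune cell markers, CD14 among them. None of 12 ciliated cell markers (group means up to 0.391 FPKM) and none of 9 red blood cell genes (up to 0.107 FPKM) reached the filter. Of 14 mucin and secretory genes only MUC1 was tested, and of 10 endothelial markers only EGFL7.

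**Figure D1:**
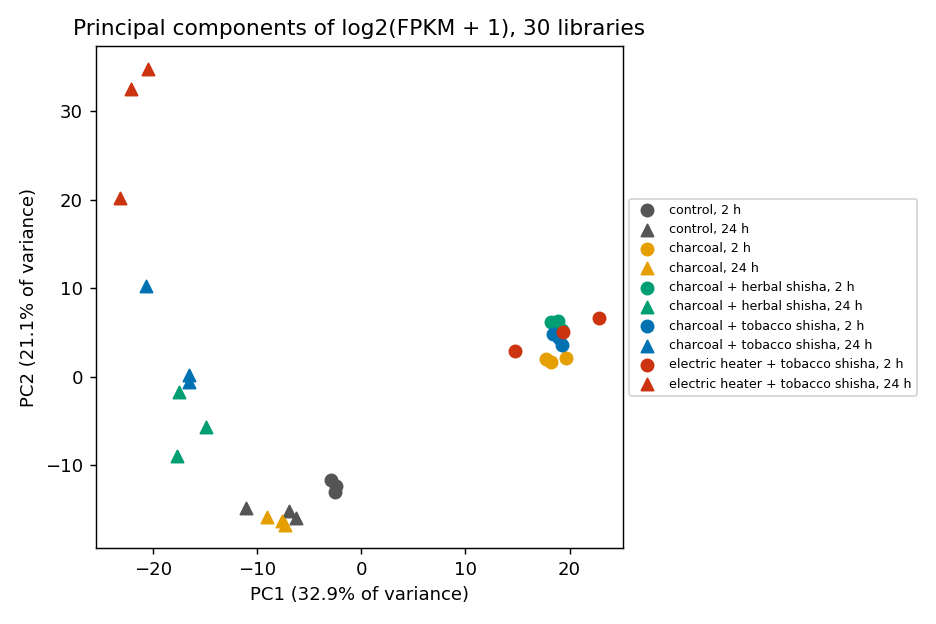
Principal components of log2(FPKM + 1) for 30 libraries, component 1 (32.9% of variance) on the horizontal axis and component 2 (21.1%) on the vertical axis. Each point is 1 library, circles at 2 h and triangles at 24 h, coloured by exposure.

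At 2 h after charcoal alone, immediate early genes stood far above control, together with AHR targets, cytokines and endoplasmic reticulum chaperones. Immediate early genes are switched on quickly after a stimulus, and many of them code for transcription factors. NR4A1, an orphan nuclear receptor (chr12:52022832-52059503), was at 58.0 ± 9.16 FPKM against 0.784 ± 0.0581 in control (SD, n = 3 wells per group here and below), a log2 change of 5.04 (SE 0.24, adjusted p = 7.22e-13). JUNB rose from 14.1 ± 0.247 to 98.2 ± 14.1 FPKM (log2 change 2.70, SE 0.12), and 22 of 23 immediate early genes rose with none falling (list adjusted p = 3.41e-33, adjusted p = 0.00719 with an estimated correlation). CYP1B1, which oxidises polycyclic aromatic hydrocarbons (chr2:38067509-38076151), rose from 11.9 ± 0.768 to 32.1 ± 1.24 FPKM (adjusted p = 2.15e-05). TIPARP, a repressor of AHR, rose from 19.1 ± 0.13 to 51.3 ± 8.44 FPKM. In all, 4 of 5 AHR targets rose (5 adjusted over the list alone; adjusted p = 1.14e-06, and 0.00719 with an estimated correlation).

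Among cytokines and NF-kB targets, charcoal alone raised 10 of 16 at 2 h and lowered 1 (11 and 1 over the list alone; adjusted p = 1.19e-09, and 0.0154 with an estimated correlation). CXCL8, a neutrophil attractant, rose from 54.7 ± 1.91 to 163.2 ± 23.1 FPKM (n = 3, adjusted p = 1.59e-10) and IL6 from 7.44 ± 0.236 to 20.4 ± 4.15 FPKM. HSPA5, the main chaperone of the endoplasmic reticulum, rose from 190.5 ± 4.75 to 316.6 ± 15.3 FPKM, with DNAJB9 and MANF. Of 10 such chaperones 5 rose and none fell (adjusted p = 9.34e-07, and 0.0064 with an estimated correlation). THBS1, a matrix glycoprotein, rose from 230.8 ± 8.65 to 684.2 ± 88.1 FPKM, and 7 of 20 matrix and mesenchymal genes rose (adjusted p = 0.000231, and 0.0454 with an estimated correlation). The largest rises after NR4A1 were DLX2 (log2 change 3.44, SE 0.22), ERRFI1, a brake on EGFR signalling (3.12, SE 0.26), ANKRD1 (3.07, SE 0.42) and IL11 (3.01, SE 0.28).

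Mitotic genes were lower 2 h after charcoal alone: TTK, a spindle checkpoint kinase, fell from 28.5 ± 0.657 to 17.8 ± 0.336 FPKM (n = 3, adjusted p = 1.17e-09), and NDC80 and CCNA2 fell by 0.65 and 0.57 log2 units. Of 22 G2/M genes 21 fell (adjusted p = 8.03e-10), a list call lost at an adjusted p = 0.188 with an estimated correlation. TXNIP, an inhibitor of thioredoxin, fell from 20.2 ± 1.47 to 4.23 ± 1.49 FPKM, and DDIT4, an mTORC1 inhibitor, by 1.39 log2 units. Among NRF2 targets 5 of 25 rose, TXNRD1 and SRXN1 with them, and 2 fell (5 and 3 over the list alone); the median was -0.04 and the mean 0.07, and the test did not pass (adjusted p = 0.0612). NQO1, HSPA1A and MT2A were not called (adjusted p = 0.571, 0.89 and 0.991). CDKN1A rose (log2 change 0.66, SE 0.09), but p53 targets as a list did not pass, with 2 higher and 6 lower, XPC and TP53INP1 among them. Altogether 2081 of 8531 genes changed, 696 higher and 1385 lower, with 148 higher and 11 lower by at least 2-fold.

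Herbal shisha on charcoal also raised immediate early genes at 2 h, with HES1, KLF10 and ATF3 among the largest rises. NR4A1 reached 61.1 ± 5.56 FPKM (n = 3, log2 change 5.12, SE 0.24). ATF3, a stress transcription factor, rose from 3.23 ± 0.545 to 55.7 ± 1.94 FPKM (adjusted p = 2.9e-10), HES1, a Notch target, from 2.81 ± 0.463 to 46.9 ± 2.92 FPKM, and KLF10 from 10.9 ± 0.513 to 133.3 ± 4.27 FPKM. Of 23 immediate early genes 21 rose (adjusted p = 8.49e-30, and 0.0111 with an estimated correlation). PPP1R15A, which reverses the translation block of the integrated stress response, rose from 28.7 ± 0.661 to 121.3 ± 3.7 FPKM; 6 of 18 genes of that response rose and 1 fell (adjusted p = 0.00159, but adjusted p = 0.178 with an estimated correlation).

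OSGIN1, SRXN1 and SLC30A1 also rose 2 h after herbal shisha on charcoal. OSGIN1 rose from 1 ± 0.285 to 5.48 ± 0.397 FPKM (n = 3, log2 change 1.70, SE 0.20), and SRXN1, a sulfiredoxin, by 0.64 log2 units. Of 25 NRF2 targets 8 rose and none fell (median 0.02; adjusted p = 0.00181, and 0.0317 with an estimated correlation). SLC30A1, a zinc exporter, rose by 1.59 log2 units (SE 0.13), and the metallothionein and zinc export list passed with 2 of 6 higher (adjusted p = 0.0112, but adjusted p = 0.178 with an estimated correlation). CYP1B1 rose to 24.6 ± 1.58 FPKM (adjusted p = 0.000523), with 3 of 5 AHR targets called (4 over the list alone; adjusted p = 0.00023, and 0.0317 with an estimated correlation). CDKN1A, a cell cycle inhibitor, rose from 41.4 ± 1.56 to 92.2 ± 3.6 FPKM. CXCL8 and IL6 rose by 1.44 and 1.42 log2 units, while NF-kB targets as a list had 5 higher and 2 lower (adjusted p = 0.00147, but adjusted p = 0.204 with an estimated correlation). DNAJB1 rose by 0.91 log2 units (SE 0.21) beside HSPA1A, which was not called (adjusted p = 0.391). Of 22 G2/M genes 17 fell, AURKA by 0.55 log2 units (list adjusted p = 6.21e-06, but adjusted p = 0.303 with an estimated correlation). The call was 3260 genes, 901 higher and 2359 lower, and 132 and 38 of these by at least 2-fold.

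Tobacco shisha on charcoal at 2 h again raised NR4A1 (58.4 ± 7.3 FPKM, n = 3, log2 change 5.05, SE 0.24), JUNB (122.7 ± 22.3 FPKM, log2 change 3.02, SE 0.12) and ATF3 (50.1 ± 14.2 FPKM, log2 change 3.56, SE 0.27). ZFP36, which destabilises cytokine mRNAs, rose from 6.52 ± 0.324 to 19.0 ± 1.31 FPKM (adjusted p = 1.58e-13). Of 23 immediate early genes 21 rose (adjusted p = 1.49e-33, and 0.00719 with an estimated correlation). CYP1B1 rose to 24.7 ± 3.14 FPKM (adjusted p = 0.000562), and 4 of 5 AHR targets rose (adjusted p = 5.53e-05, and 0.0232 with an estimated correlation). TXNRD1 rose from 147.4 ± 0.687 to 224.8 ± 11.5 FPKM; 5 of 25 NRF2 targets rose and 1 fell (adjusted p = 0.0137, but adjusted p = 0.0991 with an estimated correlation).

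The kinetochore genes CENPE and CENPF fell by 1.24 and 1.23 log2 units (SE 0.16 each, n = 3) 2 h after tobacco shisha on charcoal, and 15 of 22 G2/M genes fell (16 over the list alone; adjusted p = 5.7e-05, but adjusted p = 0.363 with an estimated correlation). VEGFA, an angiogenic factor, rose from 3.39 ± 0.514 to 12.4 ± 0.295 FPKM and ADM from 54.0 ± 3.46 to 170.6 ± 3.39 FPKM; the hypoxia list had 7 higher and 2 lower (adjusted p = 0.00132, but adjusted p = 0.313 with an estimated correlation). CXCL8 and IL6 rose by 1.14 and 1.13 log2 units, yet NF-kB targets divided into 5 higher and 4 lower (6 and 5 over the list alone), with a median of -0.17, a mean of 0.27 and no list call (adjusted p = 0.0797). NQO1 and HSPA1A were at control level (adjusted p = 0.976 and 0.992). In total 3001 genes changed, 725 higher and 2276 lower, 115 and 26 by at least 2-fold.

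Tobacco shisha on the electric heater gave the highest FOS and EGR1 levels of the 4 exposures at 2 h. FOS, a subunit of AP-1 (chr14:75278828-75282230), was at 226.5 ± 42.5 FPKM against 0.642 ± 0.142 in control (n = 3, log2 change 7.10, SE 0.29, adjusted p = 6.64e-15). EGR1, a growth-factor-induced transcription factor (chr5:138465479-138469303), was at 340.5 ± 25.5 against 1.74 ± 0.214 FPKM (log2 change 6.96, SE 0.22, adjusted p = 5.02e-17). EGR2 rose to 32.6 ± 1.68 from 0.0223 ± 0.0061 FPKM, and ZFP36 to 73.3 ± 2.32 FPKM. After charcoal alone, FOS reached only 3.5 ± 0.391 and EGR1 10.5 ± 1.3 FPKM. Of 23 immediate early genes 22 rose (median 2.71; adjusted p = 1.22e-41, and 0.00623 with an estimated correlation).

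Of the 4 exposures only the electric heater moved HSPA1A past the threshold at 2 h. HSPA1A, an inducible HSP70 (chr6:31815543-31817942), went from 14.1 ± 0.34 to 35.6 ± 6.34 FPKM (n = 3, log2 change 1.26, SE 0.27, adjusted p = 0.000816). DNAJB1, its co-chaperone, went from 56.6 ± 2.26 to 152.2 ± 17.3 FPKM (adjusted p = 1e-05). Heat shock as a list had 6 of 23 higher (adjusted p = 0.00132), not held with an estimated correlation (adjusted p = 0.59). CYP1B1 was 14.4 ± 3.36 FPKM and not called (adjusted p = 0.408); 2 of 5 AHR targets rose, TIPARP and NEDD9 (list adjusted p = 0.0131, but adjusted p = 0.178 with an estimated correlation). IL6 rose to 23.0 ± 3.26 FPKM from 7.44 ± 0.236, CXCL8 by 0.87 and IL1B by 0.72 log2 units, and ADM by 2.16. CHAC1, a glutathione-degrading ATF4 target, rose from 1.07 ± 0.197 to 5.74 ± 2.38 FPKM, and 4 of 18 genes of the integrated stress response rose (adjusted p = 0.00018, but adjusted p = 0.0991 with an estimated correlation). Oxidative phosphorylation subunits were higher in 9 of 27 cases by small amounts (10 over the list alone; median 0.14; adjusted p = 3.25e-05, but adjusted p = 0.324 with an estimated correlation). The exposure changed 2903 genes, 791 higher and 2112 lower, 130 and 12 of them by at least 2-fold.

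Several lists passed at 2 h in no exposure. Interferon response genes had at most 3 of 14 called, S phase genes 2 of 16 and cholesterol synthesis genes 4 of 14, and none of these lists passed. The p53 targets had up to 8 of 16 called, in both directions, and did not pass either, nor did epithelial junctions or the markers of immune and fibroblast cells. The excess of lower calls at 2 h depended on scale, though the scaling used centres the median of all genes and cannot decide whether the excess is real. With median-of-ratios scaling, higher and lower calls were 974 and 667 for charcoal alone, 1787 and 1505 for herbal shisha, 1656 and 1385 for tobacco shisha on charcoal, and 1581 and 1589 for the electric heater. The NR4A1, FOS and CYP1B1 changes are far larger than this shift, which moved the median change of all genes from -0.04 to -0.08 log2 units to near 0.

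**Figure D2:**
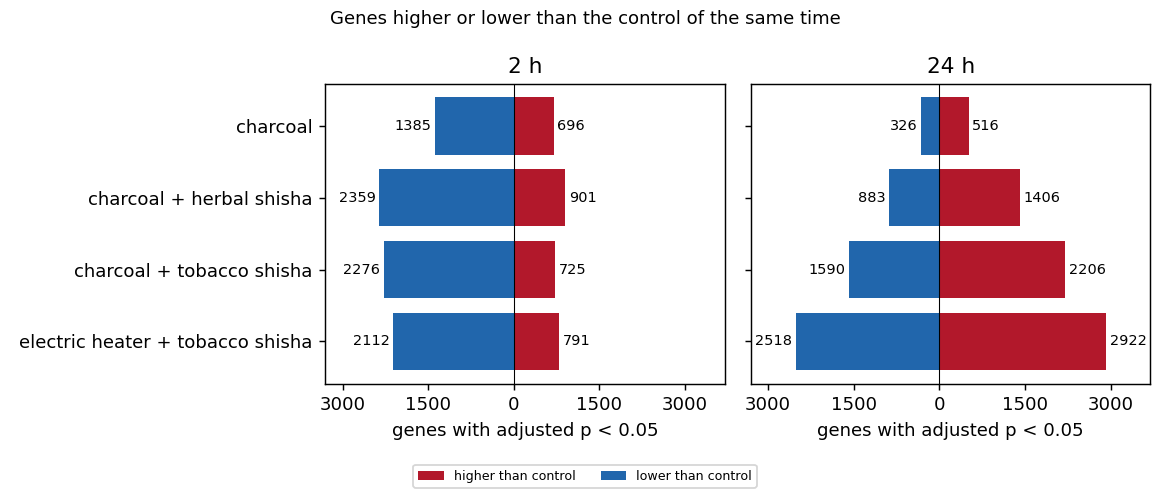
Genes higher (above zero) and lower (below zero) than control at adjusted p below 0.05 in limma, for each exposure at 2 h and 24 h, n = 3 wells per group. Bars count genes out of 8531; the electric heater at 24 h has 2922 higher and 2518 lower.

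At 2 h herbal shisha on charcoal differed from charcoal alone in HES1, FOS and EGR2. HES1 was at 46.9 ± 2.92 against 13.6 ± 2.34 FPKM (n = 3, log2 difference 1.73, adjusted p = 3.41e-05), FOS at 10.2 ± 1.45 against 3.5 ± 0.391 FPKM (1.31, adjusted p = 0.00201), and EGR2 at 3.39 against 0.673 FPKM. Immediate early genes had 9 of 23 higher (adjusted p = 0.00104, but adjusted p = 0.6 with an estimated correlation). Oxidative phosphorylation subunits had 14 of 27 higher (15 and 1 lower over the list alone; adjusted p = 8.72e-07, but adjusted p = 0.365 with an estimated correlation). CYP1B1 did not differ (adjusted p = 0.194). The count was 2083, 859 higher and 1224 lower, and 1364 without replicate 3 of herbal shisha.

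Tobacco and herbal shisha on charcoal were close at 2 h. BTG2, an antiproliferative immediate early gene, was at 4.4 ± 0.314 FPKM with tobacco against 7.27 ± 0.132 with herbal shisha (n = 3, log2 difference -0.62, adjusted p = 0.000776), and CYP1B1 was at 24.7 against 24.6 FPKM (adjusted p = 0.999). Of 16 NF-kB targets 1 was lower with tobacco (4 over the list alone; adjusted p = 2.37e-05, but adjusted p = 0.306 with an estimated correlation). Only 52 genes differed, 26 in each direction, a count resting on single wells: 15 without replicate 1 and 4 without replicate 3 of herbal shisha, and 21 and 27 without replicates 1 and 2 of tobacco. It was 7 when these 2 groups were fitted alone, and only 2 of the 52 were among these in the same direction. TXNIP (adjusted p = 0.0156) was lost in each of those fits.

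Between the tobacco exposures at 2 h, FOS was lower on charcoal than on the electric heater (4.89 ± 1.37 against 226.5 ± 42.5 FPKM, n = 3, log2 difference -5.28, adjusted p = 1.19e-11), as were EGR1 (-3.87, adjusted p = 1.27e-11) and EGR2 (-3.53). Immediate early genes had 13 of 23 lower (15 over the list alone; median -0.92; adjusted p = 7.47e-11, but adjusted p = 0.306 with an estimated correlation). CYP1B1 was higher on charcoal, 24.7 ± 3.14 against 14.4 ± 3.36 FPKM (log2 difference 0.76, adjusted p = 0.00979), with 2 of 5 AHR targets higher (3 over the list alone; adjusted p = 0.0337, but adjusted p = 0.316 with an estimated correlation). NAB2, a repressor of EGR proteins, was also higher on charcoal (73.3 ± 5.19 against 27.9 ± 10.3 FPKM), and HSPA1A lower by 1.26 log2 units (adjusted p = 0.0016). The count was 1991, 907 higher and 1084 lower on charcoal, against 1159 and 806 with median-of-ratios scaling, and 1237 without replicate 3 of tobacco on charcoal. It was 569 when these 2 groups were fitted alone.

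Control wells themselves changed between 2 h and 24 h, with hypoxia genes higher and cholesterol synthesis lower. BNIP3, a mitophagy receptor (chr10:131967684-131981923), rose from 34.7 ± 1.93 to 162.5 ± 4.2 FPKM (n = 3, log2 change 2.20, adjusted p = 4.19e-14), with NDRG1 (1.54), PDK1 (1.25) and LDHA. Of 21 hypoxia genes 18 rose (median 0.75; adjusted p = 6.93e-27, and 0.00164 with an estimated correlation). HMGCS1 fell from 68.2 ± 11.4 to 37.7 ± 5.41 FPKM, and 11 of 14 cholesterol synthesis genes fell (13 over the list alone; adjusted p = 8.4e-15, and 0.00174 with an estimated correlation). ASNS and PSAT1, enzymes of amino acid synthesis, rose by 1.23 and 1.04 log2 units, and 9 of 18 genes of the integrated stress response rose with 1 lower (10 over the list alone; adjusted p = 1.21e-06, and 0.0217 with an estimated correlation). NQO1 fell from 66.1 ± 3.25 to 39.1 ± 2 FPKM (adjusted p = 1.72e-07) and CYP1B1 from 11.9 ± 0.768 to 5.59 ± 0.832 FPKM; 8 of 25 NRF2 targets fell (adjusted p = 0.0103, and 0.0405 with an estimated correlation). The count was 1440, 635 higher and 805 lower, 885 without replicate 3 of the 2 h control, and 826 with a replicate block. With that block, coded within each time, this contrast was not one of group means, so no conclusion is drawn from the 826. Effects at 24 h are differences from this moved control.

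At 24 h after charcoal alone, the aldo-keto reductase genes AKR1C3 and AKR1B1 were higher and ASNS and PSAT1 lower than control. AKR1C3 rose from 1.92 ± 0.0691 to 7.72 ± 0.884 FPKM (n = 3, log2 change 1.57, SE 0.14, adjusted p = 2.34e-07) and AKR1B1 from 233.2 ± 21.5 to 621.5 ± 104 FPKM. NQO1, a quinone reductase (chr16:69709401-69726560), rose from 39.1 ± 2 to 63.9 ± 4.07 FPKM (adjusted p = 2.29e-06), close to the 66.1 FPKM of the 2 h control. Of 25 NRF2 targets 8 rose and 1 fell (adjusted p = 0.00159, and 0.0317 with an estimated correlation). ASNS fell from 17.7 ± 1.57 to 3.75 ± 0.112 FPKM (adjusted p = 1.24e-05) and PSAT1 from 67.7 ± 7.69 to 28.6 ± 0.958 FPKM. The integrated stress response had 10 of 18 lower, CHAC1 with them, and 1 higher, or 11 and 1 over the list alone (list adjusted p = 9.11e-12, and 0.00623 with an estimated correlation). Against the 2 h control, CHAC1 (0.25) and PSAT1 (-0.17 log2 units) were not called (adjusted p = 0.425 and 0.467 in limma), while control wells rose by 1.275 and 1.04. Below the 2 h control were ASNS (-0.74, adjusted p = 0.0486), TRIB3 (-0.53) and PHGDH (-0.32), and DDIT4 was above it (1.18).

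TAGLN, an actin-binding protein of contractile cells, fell from 769.1 ± 50.3 to 412.6 ± 11.3 FPKM (n = 3, adjusted p = 7.98e-07) 24 h after charcoal alone, while COL1A2 rose from 20.02 ± 2.53 to 33.7 ± 2.23 FPKM. Matrix and mesenchymal genes divided into 3 higher and 4 lower (adjusted p = 0.0337, but adjusted p = 0.251 with an estimated correlation), and 3 of 5 fibroblast markers were higher (adjusted p = 0.00649, but adjusted p = 0.313 with an estimated correlation). PDK1 and BNIP3 fell by 0.82 and 0.71 log2 units, with 7 of 21 hypoxia genes lower (11 over the list alone; adjusted p = 1.31e-09, but adjusted p = 0.0673 with an estimated correlation). MT2A fell from 429.8 ± 46.7 to 294.5 ± 12.6 FPKM (adjusted p = 0.00156). CCL2, a monocyte attractant, rose by 0.65 log2 units, whereas CXCL8, IL6, CYP1B1, CDKN1A and HSPA1A were not called (adjusted p = 0.353, 0.686, 0.209, 0.551 and 0.975). No heat shock gene was called in limma, where the uneven electric heater wells widen the pooled spread of genes such as HSPA1A. In total 842 genes changed, 516 higher and 326 lower (398 and 436 of 834 with median-of-ratios scaling), 9 and 7 by at least 2-fold. Without replicate 2 or 3 of charcoal the count was 523 or 511, and without control replicates 1, 2 or 3 it was 541, 556 or 555.

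Herbal shisha on charcoal raised NRF2 targets at 24 h and lowered hypoxia and junction genes. NQO1 rose from 39.1 ± 2 to 110.9 ± 5.78 FPKM (n = 3, log2 change 1.48, SE 0.07, adjusted p = 4.88e-12). GCLM, which supports glutathione synthesis, rose from 11.2 ± 1.04 to 19.7 ± 0.532 FPKM, and PRDX1, a peroxiredoxin, from 221.2 ± 3.77 to 305.6 ± 20.1 FPKM. Of 25 NRF2 targets 14 rose and none fell (adjusted p = 6.21e-06, and 0.00623 with an estimated correlation). BNIP3 fell from 162.5 ± 4.2 to 64.6 ± 11.8 FPKM (adjusted p = 9.48e-10), and 17 of 21 hypoxia genes fell (18 over the list alone; adjusted p = 8.33e-20, and 0.00719 with an estimated correlation). DHRS3, which reduces retinaldehyde (chr1:12567910-12618210), fell from 8.99 ± 1.34 to 1.27 ± 0.741 FPKM (log2 change -2.18, SE 0.15).

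DSC3, a desmosomal cadherin, fell by 0.63 log2 units (SE 0.13, n = 3, adjusted p = 0.00121) 24 h after herbal shisha on charcoal, and 7 of 11 junction and keratin genes fell (9 over the list alone; adjusted p = 3.33e-05, and 0.0317 with an estimated correlation). COL4A1, a basement membrane collagen, fell from 34.1 ± 2.26 to 18.4 ± 1.59 FPKM, and FN1 by 0.58 log2 units; 9 of 20 matrix genes fell and 1 rose (adjusted p = 0.000503, but adjusted p = 0.0609 with an estimated correlation). MUC1, the only mucin tested, fell from 3.86 ± 0.602 to 2.04 ± 0.649 FPKM. Of 14 cholesterol synthesis genes 4 fell and 1 rose (6 and 1 over the list alone; adjusted p = 0.0101, but adjusted p = 0.303 with an estimated correlation). AURKA rose by 0.43 and CCNB1 by 0.33 log2 units, with 8 of 22 G2/M genes higher and 3 lower and no list call (adjusted p = 0.202). Heat shock genes had 8 of 23 higher (9 over the list alone), STIP1 by 0.32 log2 units (list adjusted p = 0.0213, but adjusted p = 0.71 with an estimated correlation). CXCL8, IL6 and CYP1B1 were not called (adjusted p = 0.065, 0.936 and 0.101). The count was 2289, 1406 higher and 883 lower (1084 and 1017 with median-of-ratios scaling), 5 and 25 by at least 2-fold; it was 1420 without replicate 3 of herbal shisha, 1436 without control replicate 2, and 1465 when these 2 groups were fitted alone.

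Tobacco shisha on charcoal raised NRF2 targets and CXCL8 at 24 h and lowered hypoxia genes. NQO1 reached 140.3 ± 18.1 FPKM (n = 3, log2 change 1.81, SE 0.07, adjusted p = 6.08e-14) and SRXN1 rose from 37.9 ± 0.486 to 59.6 ± 5.15 FPKM. Of 25 NRF2 targets 17 rose and 1 fell (19 and 1 over the list alone; adjusted p = 8.22e-06, and 0.00623 with an estimated correlation). BNIP3 fell to 40.4 ± 0.904 FPKM (log2 change -1.98, SE 0.09), DDIT4 from 46.5 ± 1.62 to 11.6 ± 1.05 FPKM and NDRG1 from 42.2 ± 2.84 to 10.4 ± 0.966 FPKM. Of 21 hypoxia genes 19 fell and 1 rose (adjusted p = 6.34e-15, and 0.0204 with an estimated correlation). CXCL8 rose from 61.4 ± 0.969 to 114.4 ± 22.3 FPKM (adjusted p = 8.05e-07) and IL6 by 0.52 log2 units, while CXCL5 fell by 1.11; NF-kB targets divided into 6 higher and 5 lower without a list call.

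MCM6, a helicase subunit of DNA replication, fell from 42.1 ± 1.11 to 26.0 ± 5.97 FPKM (n = 3, adjusted p = 3.73e-06) 24 h after tobacco shisha on charcoal. Of 16 S phase genes 13 fell (adjusted p = 6.21e-06, but adjusted p = 0.254 with an estimated correlation). DHRS3 fell to 0.657 ± 0.254 FPKM (log2 change -2.59, SE 0.15) and MUC1 to 0.875 ± 0.283 FPKM. HIST1H2BD, a histone H2B gene, rose from 3.54 ± 0.838 to 10.9 ± 1.09 FPKM, and MMP3, a matrix metalloproteinase, from 0.171 ± 0.0586 to 2.72 ± 1.27 FPKM. COL4A2 fell from 78.6 ± 3.08 to 37.2 ± 9.18 FPKM; 9 of 20 matrix genes fell and 3 rose (9 and 4 over the list alone; adjusted p = 0.0177, but adjusted p = 0.211 with an estimated correlation). All 5 fibroblast markers were lower, THY1 by 0.25 log2 units (list adjusted p = 0.00169, but adjusted p = 0.251 with an estimated correlation). CDKN1A fell by 0.36 and BBC3 by 0.79 log2 units, with 8 of 16 p53 targets lower and 2 higher (adjusted p = 0.0154, but adjusted p = 0.239 with an estimated correlation). FKBP4 and STIP1 rose by 0.85 and 0.43 log2 units, with 12 of 23 heat shock genes higher (adjusted p = 0.0206, but adjusted p = 0.71 with an estimated correlation), although HSPA1A was not called (adjusted p = 0.548). Altogether 3796 genes changed, 2206 higher and 1590 lower (1938 and 1789 with median-of-ratios scaling), 10 and 74 by at least 2-fold.

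Tobacco shisha on the electric heater gave the widest response at 24 h, led by MMP3 and heat shock genes. MMP3 (chr11:102835801-102843609) rose from 0.171 ± 0.0586 to 140.7 ± 37.5 FPKM (n = 3, log2 change 6.88, SE 0.22, adjusted p = 4.43e-16), MMP1 from 0.048 ± 0.0439 to 13.7 ± 6.23 FPKM, and MMP10 to 11.3 ± 6.37 FPKM with controls listed at 0. HSPA1A rose from 14.2 ± 0.954 to 218.7 ± 130 FPKM (log2 change 3.63, SE 0.27, adjusted p = 1.23e-10) and HSPA6 from 0.0526 ± 0.049 to 120.9 ± 116 FPKM, with replicate 2 at 0.283 and 0.0855 of the mean of replicates 1 and 3 (MMP10 0.36). The pooled SE and p-value of HSPA1A understate the spread of these 3 heater wells. STIP1, an HSP70 and HSP90 adaptor, rose from 103.2 ± 5.38 to 271.5 ± 39.7 FPKM, and HSPD1, a mitochondrial chaperonin, from 118.1 ± 14.8 to 306.7 ± 69.3 FPKM. All 23 heat shock genes rose (median 1.37; adjusted p = 4.58e-10), although the list call was lost at an adjusted p = 0.239 with an estimated correlation. IL11 rose from 2.99 ± 0.113 to 33.8 ± 8.47 FPKM, and 19 of 23 immediate early genes, DUSP5 and IER2 with them, were still or again higher (adjusted p = 0.000584, but adjusted p = 0.448 with an estimated correlation).

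S phase and G2/M genes were lower 24 h after the electric heater exposure. MCM6 fell to 16.9 ± 1.09 FPKM (n = 3, log2 change -1.27, SE 0.09, adjusted p = 1.36e-10); all 16 S phase genes fell (adjusted p = 7.55e-09, but adjusted p = 0.178 with an estimated correlation), as did 18 of 22 G2/M genes, HMMR and KIF11 among them (adjusted p = 3.48e-06, but adjusted p = 0.291 with an estimated correlation). CDKN1A rose from 43.8 ± 3.34 to 69.8 ± 6.08 FPKM. LOX, a collagen crosslinker, fell from 15.2 ± 0.0751 to 4.4 ± 0.268 FPKM, COL1A1 from 138.1 ± 10.1 to 47.8 ± 4.4 FPKM, and GJA1, the gap junction protein connexin 43, from 17.7 ± 1.9 to 2.7 ± 0.509 FPKM. Matrix genes had 12 of 20 lower and 6 higher, with a median of -0.64, a mean of 0.16 and no list call (adjusted p = 0.0585). All 5 fibroblast markers fell (adjusted p = 0.000558, but adjusted p = 0.219 with an estimated correlation), as did 9 of 11 junction and keratin genes, PKP2 and KRT19 with them (adjusted p = 0.0158, but adjusted p = 0.232 with an estimated correlation).

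NQO1 rose to 124.2 ± 9.37 FPKM (n = 3, log2 change 1.64, SE 0.07) and SRXN1 to 84.8 ± 5.97 FPKM 24 h after the electric heater exposure, with 16 of 25 NRF2 targets higher and 3 lower (adjusted p = 0.0018, and 0.0317 with an estimated correlation). BNIP3 fell to 43.4 ± 1.3 FPKM, and 16 of 21 hypoxia genes fell (adjusted p = 6.21e-06, but adjusted p = 0.189 with an estimated correlation). ANGPTL4 of the same list went the other way: it was above the 2 h control by 2.45 log2 units, beside 0.15 in 24 h control wells. HSPA5 rose from 178.7 ± 7.35 to 298.6 ± 16.7 FPKM, yet endoplasmic reticulum chaperones did not pass as a list (4 higher, 2 lower), and the integrated stress response divided into 7 higher and 7 lower. PHGDH, which starts serine synthesis, fell from 111.0 ± 2.67 to 50.6 ± 0.89 FPKM, and MT2A from 429.8 ± 46.7 to 270.8 ± 4.33 FPKM. ISG15 and DDX58 rose by 0.45 and 0.40 log2 units, with 4 interferon genes higher and 3 lower and no list call. CXCL8 rose by 0.36 log2 units (adjusted p = 0.00432), CXCL5 fell by 1.54, and CYP1B1 was not called (adjusted p = 0.074). The count of 5440 changed genes, 2922 higher and 2518 lower, was the largest of any exposure, with 188 and 221 by at least 2-fold.

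**Figure D3:**
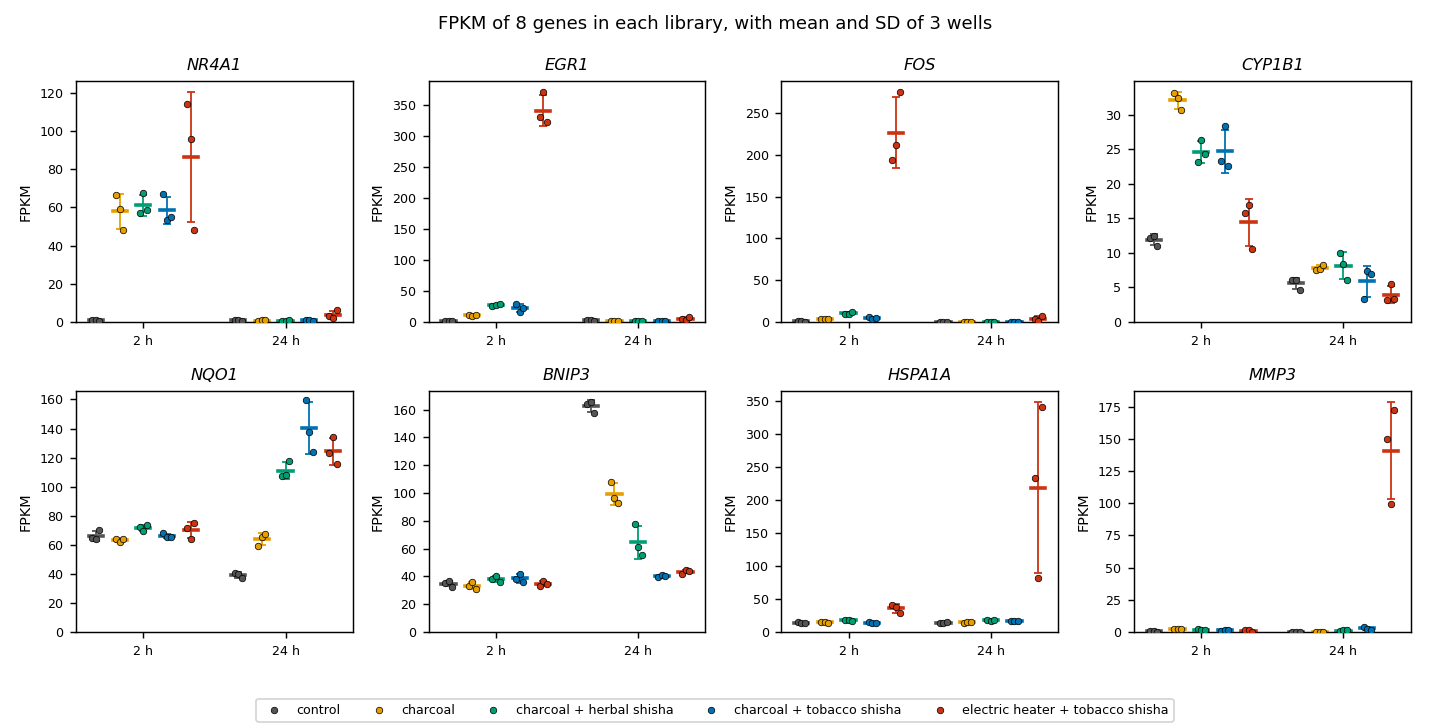
FPKM of NR4A1, EGR1, FOS, CYP1B1, NQO1, BNIP3, HSPA1A and MMP3 in each of 30 libraries by exposure and time. Points are wells, lines are group means with SD (n = 3); NQO1 at 24 h runs from 39.1 FPKM in control to 140.3 with tobacco on charcoal.

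**Figure D4:**
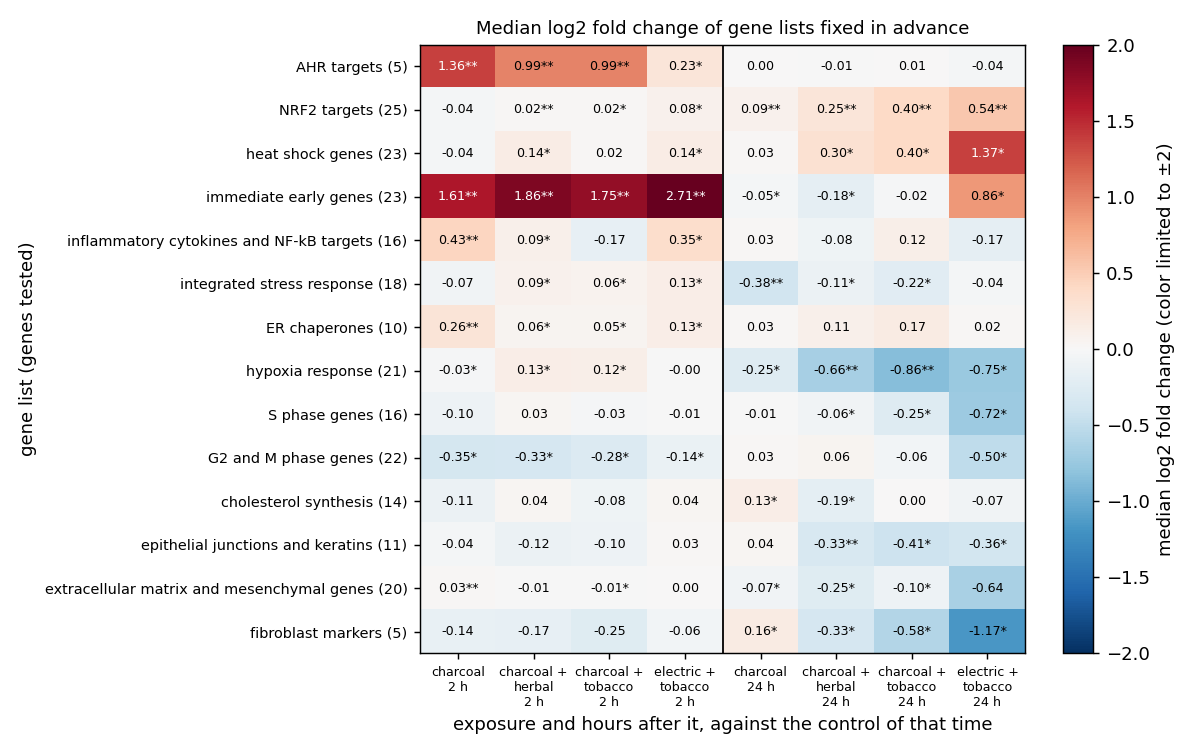
Median log2 change of 14 gene lists (vertical) in 8 comparisons with control (horizontal), colour limited at 2 log2 units. A single star marks a camera adjusted p below 0.05 and a double star the same with an estimated correlation, as for immediate early genes at 2 h (medians 1.61 to 2.71).

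Herbal shisha on charcoal and charcoal alone parted at 24 h. DHRS3 was at 1.27 ± 0.741 with herbal shisha against 14.1 ± 0.836 FPKM with charcoal alone (n = 3, log2 difference -2.78, adjusted p = 1.65e-11), and the retinoid-responsive RARRES1 at 0.909 ± 0.498 against 6.25 ± 0.231 FPKM. Against control, charcoal alone raised DHRS3 by 0.60 (adjusted p = 0.00977) and RARRES1 by 0.94 log2 units (adjusted p = 0.000503). ASNS was higher with herbal shisha by 1.88 log2 units (adjusted p = 4.98e-06) and NQO1 by 0.79 (adjusted p = 1.26e-07), and 10 of 18 genes of the integrated stress response were higher with 1 lower (adjusted p = 0.00513, but adjusted p = 0.316 with an estimated correlation). Hypoxia genes were lower in 15 of 21 cases, junction and keratin genes in 9 of 11 and cholesterol synthesis genes in 10 of 14; these list calls (adjusted p = 6.24e-07, 4.91e-05 and 0.000135) were lost at adjusted p = 0.306, 0.246 and 0.306 with an estimated correlation. The count was 2687, 1381 higher and 1306 lower, and 1770 without replicate 3 of herbal shisha. Against the 2 h control, ASNS at 24 h was at 1.13 log2 units with herbal shisha, 1.23 in control wells and -0.74 after charcoal alone.

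Tobacco differed from herbal shisha on charcoal in BNIP3 and NQO1 at 24 h. BNIP3 was at 40.4 ± 0.904 against 64.6 ± 11.8 FPKM (n = 3, log2 difference -0.65, adjusted p = 0.000529) and NQO1 at 140.3 ± 18.1 against 110.9 ± 5.78 FPKM (0.33, adjusted p = 0.0119), while DHRS3 did not differ (adjusted p = 0.0946). Of 25 NRF2 targets 5 were higher (adjusted p = 0.0043, but adjusted p = 0.246 with an estimated correlation) and of 16 S phase genes 7 lower (13 over the list alone; adjusted p = 2.16e-09, but adjusted p = 0.306 with an estimated correlation). SPAG4, CLDN1 and IL18 were called here too (adjusted p = 0.000529, 0.00363 and 0.00754). Neither these genes nor BNIP3 and NQO1 were called when these 2 groups were fitted alone. The count of 437, 206 higher and 231 lower, moved with single wells: 45 without replicate 1 and 746 without replicate 3 of tobacco, and 150, 130 and 692 without replicates 1, 2 and 3 of herbal shisha. No gene was called by limma in the fit of these 2 groups alone, where 1052 had an unadjusted p below 0.05.

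Between the tobacco exposures at 24 h, MMP3 was lower on charcoal than on the electric heater by 5.27 log2 units (n = 3, adjusted p = 1.63e-13) and HSPA1A by 3.42 (adjusted p = 3.53e-09). All 23 heat shock genes were lower on charcoal (adjusted p = 8.99e-14, but adjusted p = 0.306 with an estimated correlation), as were 19 of 23 immediate early genes. NPPB, a natriuretic peptide gene, was higher on charcoal, 156.5 ± 15 against 32.3 ± 5.7 FPKM, and THBS1 180.6 ± 22.4 against 72.3 ± 4.23 FPKM. Of 22 G2/M genes 19 were higher on charcoal (20 over the list alone; adjusted p = 3.66e-10, but adjusted p = 0.306 with an estimated correlation), and 18 of 27 oxidative phosphorylation subunits (adjusted p = 4.96e-06, but adjusted p = 0.405 with an estimated correlation). NQO1 and BNIP3 did not differ (adjusted p = 0.0628 and 0.371). The count was 4078, 2123 higher and 1955 lower, and 2559 when these 2 groups were fitted alone; the highest count of any other split of the same wells was 1629.

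More genes were called in the same direction in all 4 exposures than independent calls would give. At 2 h 256 genes were higher in all 4, NR4A1, JUNB and ATF3 among them, against 0.579 if calls were independent, and 651 lower, TTK and CCNA2 among them, against 25.3. At 24 h 120 were higher, NQO1 among them, against 7.53, and 93 lower, BNIP3 among them, against 1.86. With median-of-ratios scaling, chosen after seeing the data, 377 (7.34 if independent) were higher and 320 (3.56) lower at 2 h, then 77 (3.73) and 118 (3.4) at 24 h. Which direction had more shared calls thus changed with this scaling, which centres the median of all genes and so cannot decide it. The 4 exposures share control wells, so part of this excess may come from shared controls. With 3 wells per control group they could not be divided. What the control wells received is not known here. Handling common to the 4 exposures but absent from control wells therefore cannot be told apart from smoke as a source of shared calls, immediate early genes included. Simulation with shared controls and no effect gave a correlation of changes of 0.501 between herbal and tobacco shisha on charcoal at 2 h, where the real value was 0.873, and a covariance of 0.0117 against 0.118. At 24 h the values were 0.486 against 0.808, and 0.0112 against 0.0663. Charcoal alone and herbal shisha at 24 h had a covariance of 0.0126, little above the 0.0112 of shared controls alone. Their correlation of 0.244 was below the 0.492 of the simulation. They shared 157 higher (85.0 if independent) and 106 lower calls (33.7), and 92 genes were called in opposite directions, DHRS3 and RARRES1 among them. With tobacco on charcoal and the electric heater, charcoal alone correlated at 0.232 and 0.176 at 24 h, below the simulated 0.495 and 0.488. The covariances were 0.0156 and 0.0188, against a simulated 0.0114 and 0.0112. Whether charcoal alone shared a 24 h response with the other exposures therefore stays open.

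The exposure effect on NQO1 was larger at 24 h than at 2 h in every exposure, by 0.76 log2 units after charcoal alone (SE 0.10, n = 3, adjusted p = 1.15e-05), 1.37 with herbal shisha, 1.81 with tobacco on charcoal and 1.56 on the electric heater. BNIP3 had the opposite course against the control of the same time, not called at 2 h anywhere and lower at 24 h, with differences of -0.65, -1.47, -2.13 and -1.89. In control wells BNIP3 itself rose by 2.20 log2 units between the times, and NQO1 fell. Exposed wells at 24 h were still above the 2 h control in BNIP3, by 1.49, 0.87, 0.22 and 0.32 in the same order. BNIP3 thus rose less than in control wells and did not fall below the 2 h control. JUNB differed by -2.75 to -3.29, its early rise being gone by 24 h except on the electric heater (log2 change 0.41, adjusted p = 0.00445). TXNRD1 rose at 2 h and was not called at 24 h in the 3 charcoal exposures (adjusted p of the difference 0.000102, 0.000309 and 0.000149). Effects differed between the times in 1979, 2756, 3502 and 4918 genes for charcoal alone, herbal shisha, tobacco on charcoal and the electric heater, with 69.8%, 74.3%, 73.7% and 60.4% higher at 24 h. With median-of-ratios scaling these shares were 42%, 44.9%, 47% and 50.8%. This scaling centres the median of all genes and so largely fixes the share. Whether the excess is real or a matter of scale therefore cannot be told. Genes called at both times numbered 203, 871, 1344 and 1906, and 86, 577, 867 and 1138 of these kept their direction.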

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

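Effects of the exposures differed between 2 h and 24 h by a test of the difference itself. The tests of single hypoxia genes against the 2 h control and of scaling for the lower calls at 2 h were chosen after their results were seen, as were all alternatives with median-of-ratios scaling.

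Between the times, the effect differed for 1979 genes after charcoal alone, 2756 with herbal shisha, 3502 with tobacco shisha on charcoal and 4918 with the electric heater. Genes called higher at 2 h and lower at 24 h numbered 32, 85, 86 and 114 in the same order (60, 158, 203 and 404 with median-of-ratios scaling). Those lower at 2 h and higher at 24 h numbered 85, 209, 391 and 654 (31, 80, 161 and 422 with that scaling). Among genes chosen after their values were seen, MYADM, a membrane protein gene, went from 2.59 at 2 h to -0.49 log2 units at 24 h after charcoal alone (adjusted p of the difference 1.52e-09), and from 1.83 to -1.12 with the electric heater (adjusted p = 5.78e-10). VEGFA went from 1.61 to -0.97 with tobacco on charcoal, and AURKA from -0.55 to 0.43 with herbal shisha. These are changes from the control of the same time. Against the 2 h control, VEGFA at 24 h with tobacco on charcoal was not called (-0.10, adjusted p = 0.504 in limma), while control wells rose by 0.86. NPPB went from 0.72 to -2.53 and SLC6A8 from -0.26 to 1.28 with the electric heater.

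With labels exchanged within each time, 1 of 100 splits, the real one, gave as many genes for charcoal alone (1979 against a highest other of 1093). The real one included, 2 of 100 each did so for herbal shisha (2756 against 3501), tobacco on charcoal (3502 against 4053) and the electric heater (4918 against 5047). Such splits also break up the exposure effects at each time. A low share therefore cannot show that the effects differ between the times, and no conclusion is drawn from it. The higher value in the last 3 came from exchanging exposed and control labels at 1 time only, which adds the effects of the 2 times instead of subtracting them and reflects a structure of the samples. Apart from that exchange, the highest counts of other splits were 2528, 2253 and 4175 in the same order, so counts not far below the real ones arose with mixed wells for herbal shisha and the electric heater.

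Lower calls outnumbered higher ones at 2 h in all 4 exposures. With median-of-ratios scaling the lowest share of higher calls was 49.9%, but this scaling centres the median and so fixes the share. Strongly raised genes took at most 2.65 percentage points more of the FPKM total than in control, too little to decide either way. Whether the lower calls come from scale or from a real fall of many genes cannot be told apart.

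Hypoxia genes were below the 24 h control after every exposure, and scaling of FPKM values is argued against as the source, as the list median nearest 0 was still -0.279 after scaling. For a rise in the 24 h control wells alone, the planned test asked for a list median at or above 0 in exposed wells at 24 h against the 2 h control. It was met, with 0.0288 for tobacco on charcoal, 0.149 for herbal shisha, 0.254 for the electric heater and 0.485 for charcoal alone, beside 0.747 in control. A rise in exposed wells meets this criterion too, so the result does not favour a rise in control wells alone. Tests of single genes argue against it for charcoal alone, where 16 of 21 genes were called higher than in the 2 h control and 0 lower (18 higher in control), and for the electric heater, where 9 were higher and 7 lower, LOX and PFKFB4 among the lower. With tobacco on charcoal 3 were higher and 4 lower, SLC2A1 and PFKFB4 among the lower, and with herbal shisha 6 and 2 (limma), so in these exposures a rise in control wells alone is argued against for the called genes and stays open for the others. Cell number and oxygen use were not analysed here.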

How the results depend on the processing

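Median-of-ratios scaling, leaving out genes listed at 0, summing repeated names, the robust spread and, for counts, a pseudocount of 0.1 were chosen after the data were seen. The count-based tests and size factors were not run, since the values are FPKM.

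The counts against control at 2 h, and those of tobacco on charcoal and the electric heater at 24 h, stayed within 1.5 times under every alternative except a minimum change of 2-fold. The genes behind the 2 h counts were less stable. With median-of-ratios scaling, 1363 of 2081 genes for charcoal alone and 2406 of 3260 for herbal shisha were called again in the same direction. For tobacco on charcoal these were 2110 of 3001, and for the electric heater 2380 of 2903. At 24 h the last 2 exposures kept 3528 of 3796 and 5285 of 5440. With the replicate block, the control count between the times was 826 and no other count moved past 1.5 times. The blocks were coded within each time, so in that fit this contrast set reference replicates of the 2 times against each other, not group means. The 826 therefore says nothing about how firm the control change is. Replicate numbers did not pair the wells (6 of 60 pairs correlated above 0.1, range -0.11 to 0.23).

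Fitting the compared groups alone gave 1465 for herbal shisha at 24 h, 569 and 2559 for tobacco on charcoal against the electric heater at 2 h and 24 h, and 7 and 0 for tobacco against herbal shisha (limma, 1052 at an unadjusted p below 0.05, lowest adjusted p = 0.232). Such fits estimate spread from fewer libraries.

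A minimum change of 2-fold left 159, 170, 141 and 142 genes at 2 h for charcoal alone, herbal shisha, tobacco on charcoal and the electric heater, and 16, 30, 84 and 409 at 24 h. It left 38 and 59 for herbal shisha against charcoal alone at 2 h and 24 h, 4 and 3 for tobacco against herbal shisha, 61 and 120 between the tobacco exposures, 27 between the controls, and 188, 206, 213 and 483 for the differences between times.

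Leaving out 1 library gave 511 (without charcoal replicate 3) to 602 for charcoal alone at 24 h, and 1420 (without herbal replicate 3) to 2317 for herbal shisha at 24 h. Herbal shisha against charcoal alone ranged over 1364 (without herbal replicate 3) to 1807 at 2 h and 1770 (without herbal replicate 3) to 2859 at 24 h. Tobacco against herbal shisha ranged over 4 (without herbal replicate 3) to 57 at 2 h and 45 to 746 at 24 h (without tobacco replicates 1 and 3). The tobacco exposures at 2 h ranged over 1237 (without replicate 3 on charcoal) to 1991, and the controls over 885 (without 2 h replicate 3) to 1071. The cause was not tested beyond the smaller number of libraries.

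Of 528 values of named genes, none that was called changed sign with scaling. Uncalled ones that did had log2 changes of 0.087 for MT2A and 0.026 for NQO1 (charcoal alone, 2 h), 0.11 for HSPA1A and 0.075 for MT2A (tobacco on charcoal, 2 h), -0.00027 for HSPA1A (charcoal alone, 24 h) and -0.013 for CYP1B1 (tobacco on charcoal, 24 h). Calls were lost in 30 with scaling, 53 with the compared groups alone, 35 without the filter, 15 with a pseudocount of 0.1, 6 with the block, 9 with the robust spread and 5 with summed names. Leaving out genes listed at 0 kept all 502 that could be compared.

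Leaving out 1 library lost the call in 335 of 3168 values and turned the sign in 18, all of genes not called with every library. For MT2A the log2 change ran from -0.0195 to 0.019 (charcoal alone, 2 h), -0.118 to 0.0812 (tobacco on charcoal, 2 h), -0.0245 to 0.217 (herbal shisha, 24 h) and -0.0924 to 0.0499 (tobacco on charcoal, 24 h). For HSPA1A it ran from -0.0746 to 0.0554 (tobacco on charcoal, 2 h) and -0.000623 to 0.0786 (charcoal alone, 24 h), for NQO1 from -0.0164 to 0.0438 (tobacco on charcoal, 2 h), for IL6 from -0.105 to 0.0653 (herbal shisha, 24 h) and for CYP1B1 from -0.158 to 0.319 (tobacco on charcoal, 24 h).

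Of 152 list tests against control, 74 passed at the preset correlation, 19 of them with an estimated correlation, 65 with fry, 72 with the block and 67 with scaling, and no direction turned. The number of reads behind each value is unknown, so limits set by depth could not be given.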

Other observations

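The 4 added gene lists were chosen after the first results were seen, with predictions written before their own results; the test of control RNA in replicate 2 was chosen after its result was seen. Genes that had drawn attention (DHRS3, RARRES1, ANKRD1, HIST1H2BD and HIST1H2AC) were left out of them.

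Some retinoic acid responsive genes were lower 24 h after tobacco shisha on charcoal, with RARRES3, TGM2 and RARRES2 down by 0.78, 0.80 and 0.60 log2 units (SE 0.15, 0.15 and 0.12, n = 3). Of 6 tested genes 4 fell, 66.7% (adjusted p = 0.0179 over 32 tests), and the same number with herbal shisha (adjusted p = 0.0186). After charcoal alone 3 rose and TGM2 fell (adjusted p = 0.028). With an estimated correlation each of the 3 had an adjusted p = 0.214. With the electric heater RARRES2, RARRES3 and RARG fell, CRABP2, which carries retinoic acid to its receptor, rose by 1.55, and the list did not pass (adjusted p = 0.615). Lower retinoic acid signalling is a candidate explanation for the fall of DHRS3 after tobacco shisha on charcoal, found and tested on the same data.

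Ribosome biogenesis genes rose 24 h after the electric heater exposure, opposite to the replication genes. NOP2, a ribosomal RNA methyltransferase, rose by 1.16 log2 units (SE 0.06, n = 3, adjusted p = 8.01e-13) and RRP9 by 1.18 (SE 0.09). Of 14 genes 12 rose and 0 fell (list adjusted p = 0.000286, but adjusted p = 0.214 with an estimated correlation), against a prediction that they would fall with proliferation. With tobacco on charcoal 6 rose and 1 fell (adjusted p = 0.028, but adjusted p = 0.492 with an estimated correlation).

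Histone cluster genes were higher 24 h after tobacco on charcoal in 11 of 26 cases and lower in none, 42.3%, short of the general rise predicted (adjusted p = 0.01, but adjusted p = 0.36 with an estimated correlation). Charcoal alone raised 9 (adjusted p = 0.000286, but adjusted p = 0.214 with an estimated correlation). Herbal shisha raised 8 (adjusted p = 0.00364, but adjusted p = 0.324 with an estimated correlation). The electric heater raised 12 with 2 lower, and the list did not pass (adjusted p = 0.218). Beside ANKRD1, 3 of 11 other YAP and TEAD targets rose at 2 h after each exposure, 27.3%, under the 50% predicted for activation after every exposure, and 3 fell with herbal shisha, 4 with tobacco on charcoal and 2 with the electric heater. After charcoal alone none fell and the list passed (adjusted p = 0.0134, but adjusted p = 0.275 with an estimated correlation). With the electric heater 7 of the 11 were lower at 24 h (adjusted p = 0.028, but adjusted p = 0.36 with an estimated correlation).

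Replicate 2 of the electric heater at 24 h had less of the heat shock and metalloproteinase induction, with HSPA1A at 0.283, HSPA6 at 0.0855 and MMP1 at 0.417 of the mean of replicates 1 and 3. Control RNA mixed into that library would weaken raised and lowered genes alike: 378 other genes changed 2-fold kept a median of 0.85 of their effect, but 163 raised ones 0.626 (quartiles 0.428 to 0.819) and 215 lowered ones 0.899 (0.833 to 0.962), against 0.369 for 23 pattern genes (0.266 to 0.498). The lowered genes argue against such a mix as the whole source, while other raised genes were weaker in this well too and a small share of control RNA stays open. Scaling left the median ratio of the pattern genes at 0.533 (0.55 unscaled). Reads shared between paralogs are argued against by 17 other heat shock genes, at a median ratio of 0.561. No biological explanation was tested within a group, and a different dose in that well stays open.

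The 10 splits of 6 libraries are too few for a share under 0.05. In every comparison 1 of the 10, the real one, gave as many genes. The other splits mix wells of the 2 groups, which puts the effect itself into the spread. Their low counts are thus largely fixed in advance, and no conclusion is drawn from them. Real and highest other counts against control at 2 h were 2081 and 2 for charcoal alone, 3260 and 1 for herbal shisha, 3001 and 1 for tobacco on charcoal, and 2903 and 2 for the electric heater. At 24 h they were 842 and 1, 2289 and 6, 3796 and 3, and 5440 and 0 (limma, 515 at an unadjusted p below 0.05). Herbal shisha against charcoal alone gave 2083 and 2 at 2 h and 2687 and 1 at 24 h, and tobacco against herbal shisha 52 and 1, then 437 and 53. The tobacco exposures gave 1991 and 2 at 2 h, then 4078 and 1629, and the controls 1440 and 1. The split with 1629 set replicate 1 on charcoal with replicates 1 and 3 on the heater against the rest, so wells of both groups differ among themselves, replicate 1 on charcoal and replicate 2 on the heater each lying apart from the other wells of its group.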
